A study of Mus musculus with 4 samples.

How the data were processed

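Nuclei from medial prefrontal cortex of 4 mice were profiled with 10x Genomics chemistry reading the 3' end of transcripts, per the labels. The deposited values are UMI counts per feature and barcode, whole numbers in 1 pooled matrix with no normalization visible. Per the file headers and the submitters' processing notes, the authors made it with Cell Ranger 7.1.0 on genome build mm10, to which 2 transgene features, TREmcherry and tTA, had been added. How barcodes were chosen, and whether reads were subsampled when libraries were joined, is not known here. Barcodes end in a number from 1 to 4 that separates libraries. No file used here ties an ending to a sample, and none was inferred from order or values. By the rule set for that case before the data were examined, the matrix was treated as 1 sample: no test between DOI and saline, or between sexes, was run.

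Barcodes were kept with at least 500 genes, at least 800 UMIs and at most 5% mitochondrial UMIs. This removed 9132 of 22402 barcodes (1418, 1724, 1480 and 4510 in libraries 1 to 4), of which 8638 exceeded the mitochondrial limit. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, and 388 barcodes above a score of 0.25 were removed. That single score was set after the automatic threshold had failed in library 4, where it was 0.5558 and marked 4 doublets. The 12882 remaining nuclei had a median of 8858.5 UMIs and 3315 genes. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes, without sex-linked, mitochondrial and list genes, gave 30 principal components, a graph of 15 neighbours and, by the Leiden method at resolution 1.0, 22 clusters. Clusters were named from 32 fixed marker lists by their enriched markers, with at least 3 markers each at least 2-fold enriched and at 10 CPM or more. A cluster without such markers, or led by globin genes, stayed unnamed within its kind. The same held where a second type scored above 0.85 times the best score. It also held for a shallow cluster with no marker of its type among its 10 leading genes. Names mean resemblance to a class, and the genes that define a class are not results. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used, with a fixed seed. Gene positions and overlaps came from GENCODE M21.

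UMIs were summed over the nuclei of a class and divided by the class total to give CPM. The ratio of 2 classes has an exact conditional binomial 95% interval and was also computed in each library. Shares have exact binomial (Clopper-Pearson) 95% intervals. These intervals cover counting error only, not differences between animals or between nuclei. There were 13 class comparisons over 157 genes in 11 lists fixed beforehand: serotonin receptors, Gq signalling, immediate early genes, late activity and plasticity genes, neurotrophin genes, ionotropic and metabotropic glutamate receptors, GABA-A subunits, postsynaptic scaffold and kinase genes, other monoamine, opioid, cannabinoid and muscarinic receptors, and stress and glucocorticoid response. A gene was called higher or lower when it had at least 100 UMIs in the nuclei compared, a ratio of at least 2 or at most 0.5, and the same sign in all 4 libraries. A library with UMIs on 1 side alone counts with that side. This is a rule of size, not a test, and no p-value was made from nuclei. A list's median log2 ratio was placed among 10000 random lists matched on mean expression. Genes of a random list were drawn independently, while genes of a fixed list may vary together. A percentile can therefore overstate how unusual a median is, and it is a description, not a test. Genes eligible to be named were at most the 3 largest called genes per list, all serotonin receptors with at least 50 UMIs, and, over all genes with at least 500 UMIs outside the marker lists and without predicted, mitochondrial or ribosomal names, the 10 largest ratios, 5 per direction. For subclasses the text gives the first of these on the higher side that no list holds. Each subclass was compared with the named subclasses of its kind, without nuclei of no subclass. The Htr2a shares of nuclei were chosen after other values had been seen.

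The reporter was read as the share of nuclei with at least 1 TREmcherry UMI, beside shares after thinning each nucleus to 1500 UMIs. Positive and negative nuclei were compared in classes with at least 50 positive nuclei.

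The calling rule was tested on simulated data with known changes in 200 genes. For excitatory against inhibitory nuclei it called 67 of 67 genes with a 3-fold change, 64 of 66 with a 4-fold change, 1 of 67 with a 1.5-fold change and 28 of 15582 unchanged genes. For L6b it called 56 of 67 with a 3-fold change and 329 of 15018 unchanged genes, and for Vip 62 of 67 and 19 of 10015. The simulated counts were Poisson draws with the same rate in every library, so they held counting error only. Differences between libraries or nuclei were not simulated, and wrong calls in the real data may be more frequent.

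Several list genes overlap another annotated gene, among them Baz1a and Grin3a on the same strand, and Fosl1, Gabra5, Grin2d, Grk5, Homer3, Hspa1a, Htr2b, Nrn1, Oprm1, Plcb3 and Prkca on the opposite strand. Their values are uncertain to the extent that reads of the neighbour were assigned to them. Alternatives tried were resolutions 0.5 and 2.0, doublets kept, at least 1000 genes and 1500 UMIs, at most 1% mitochondrial UMIs, 4000 variable genes, each library left out, means over nuclei or over libraries, thinning, CPM without mitochondrial and the 20 most abundant genes, random lists without marker genes, and a reporter minimum of 2 UMIs. Alternatives chosen after seeing the data were a limit of 20% mitochondrial UMIs and automatic doublet thresholds. For the reporter they were leaving out nuclei of more than 5 TREmcherry UMIs, and ratios within libraries. Other settings for DOI against saline were not run because no barcode could be assigned to a sample.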

Results

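Single-nucleus RNA sequencing was done on medial prefrontal cortex of C57BL/6J mice, 9 weeks old, 24 hours after an injection of DOI or saline. DOI is a psychedelic that activates the serotonin receptors encoded by Htr2a and Htr2c. The tissue expressed scFLARE2, a light- and calcium-gated tool that releases the transcription factor tTA in active cells, and a TRE reporter coding for mCherry and the opsin bReaChES. The labels give 4 samples, 2 of them DOI and 2 saline, with 1 female and 1 male in each group. The pooled matrix held 22402 barcodes, 32287 features and 157575088 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule). Barcode endings separated 4 libraries, here called libraries 1 to 4, of 5721, 5278, 3076 and 8327 barcodes. Their total counts were 40322155, 39336793, 19968985 and 57947155 UMIs. The endings name no sample, so the matrix stood for 1 sample in what follows. No DOI group was compared with a saline group, and no sex with the other. The values below describe cell classes within these libraries, which were not treated as replicates, and no test between animals was made. Intervals are 95% and cover counting error only.

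After filtering, 12882 nuclei remained, with 4173, 3446, 1567 and 3696 from libraries 1 to 4. The first question was which cell types of the dissected tissue the nuclei came from. Excitatory neuron-like nuclei made up 64.0% (exact binomial interval 63.2 to 64.8, 8247 nuclei), inhibitory neuron-like nuclei 10.1% (9.63 to 10.7, 1307 nuclei) and non-neuronal nuclei 21.5% (20.8 to 22.2, 2771 nuclei). Deep-layer cells led the excitatory nuclei, with 2482 L6 CT-like (corticothalamic) nuclei. There were 1356 L2/3 IT-like (intratelencephalic) nuclei, 1226 L5 IT-like, 1111 L6 IT-like, 937 L5 ET-like (extratelencephalic), 419 L5/6 NP-like (near-projecting) and 179 L6b-like nuclei, and 537 with no subclass. The inhibitory nuclei comprised 544 Pvalb-like, 423 Sst-like, 232 Vip-like and 108 Lamp5-like nuclei. Among glia there were 973 oligodendrocyte-like, 572 astrocyte-like, 548 microglia-like and 369 oligodendrocyte precursor-like nuclei, and 94 committed precursor-like nuclei. A further 330 nuclei resembled striatal medium spiny neurons and 227 resembled neuroblasts. The excitatory share was 61.9%, 59.6%, 55.6% and 74.1% in libraries 1 to 4, and the non-neuronal share ranged from 14.6% to 31.9% with a median of 23.0%. Shares depended on the limit for mitochondrial UMIs. With at most 1% in place of 5%, the non-neuronal share was 3.99% and the excitatory share 84.1%.

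**Figure D1:**
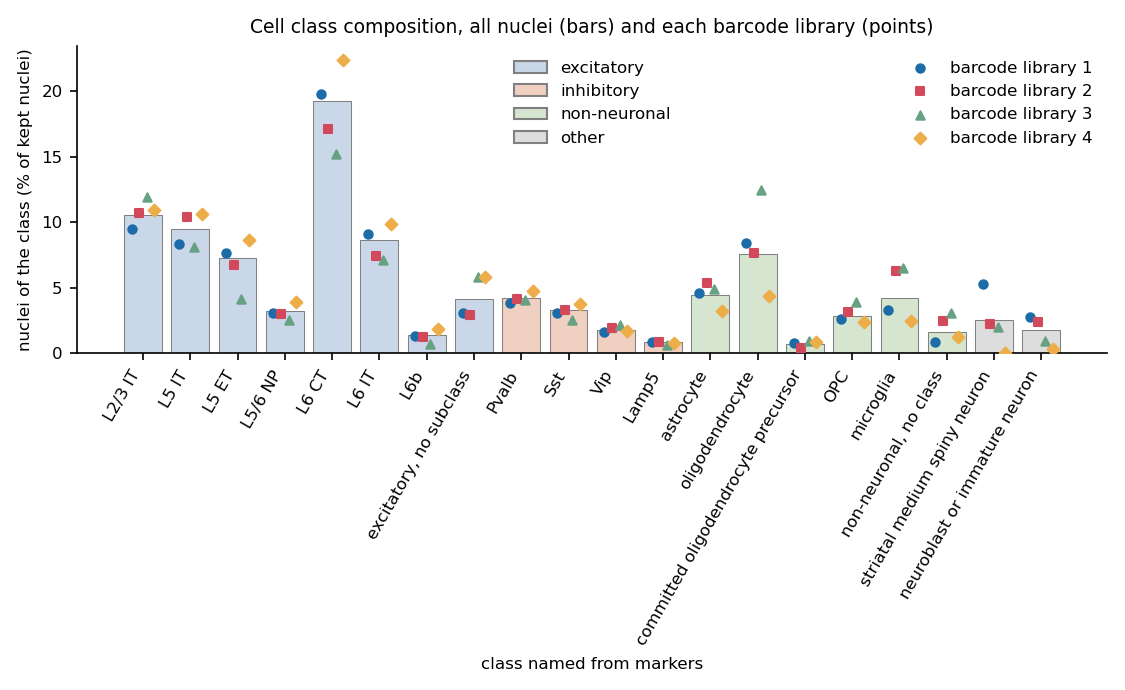
Share of kept nuclei in each class named from markers, in percent, for all nuclei (bars) and for each barcode library (points). L6 CT-like nuclei form the tallest bar at 19.3%, and striatal medium spiny neuron-like nuclei range from 0.027% in library 4 to 5.27% in library 1.

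Transcripts typical of neurons were found in glial classes, and their source was not tested. Slc17a7, the vesicular glutamate transporter of excitatory neurons, stood at 247 CPM (UMIs of a gene scaled to a fixed total per class) in excitatory nuclei and at 234 CPM in microglia-like nuclei, whose median depth was 2413 UMIs against 10884 in excitatory nuclei. Gad1, a GABA-synthesising enzyme, reached 15.9% of its inhibitory level in microglia-like nuclei.

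The second comparison set excitatory against inhibitory nuclei, to ask which neurons carry the receptors through which a psychedelic acts. Htr1f was higher in excitatory nuclei, at 302 against 140 CPM, a log2 ratio of 1.10 (1.03 to 1.17). Htr2c was lower, at 51.0 against 137 CPM (log2 ratio -1.43, -1.51 to -1.35), and so was Htr7, at 5.18 against 22.7 CPM (-2.13, -2.34 to -1.91). Each of these directions was present in 4 of 4 libraries. Htr2a, the main target of DOI, was at a like level in both kinds, at 43.3 CPM in excitatory and 50.4 CPM in inhibitory nuclei (log2 ratio -0.22, -0.34 to -0.10), under the 2-fold size required. Of the 10 serotonin receptor genes with at least 100 UMIs, 1 was higher in excitatory nuclei, 2 were lower and 7 missed that size. Among those 7, the log2 ratio was 0.88 for Htr1b, 0.38 for Htr6, 0.13 for Htr2b, -0.25 for Htr1a, -0.32 for Htr4 and -0.38 for Htr5a. Htr3a had 16 excitatory and 40 inhibitory UMIs, Htr1d 74 and 11, and Htr5b 50 and 2, too few for the size rule. Htr2b overlaps Psmd1 on the opposite strand, so the origin of its UMIs is uncertain. The Htr2c ratio was -0.38 at a clustering resolution of 0.5 and -0.42 with up to 20% mitochondrial UMIs. In these settings Vip-like and Lamp5-like nuclei were not named, and the inhibitory side held only nuclei named Pvalb-like or Sst-like. These ratios therefore compare a different set of inhibitory nuclei.

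On genome build mm10, Htr2a (ENSMUSG00000034997) lies on chromosome 14 from 74640840 to 74709494 and Htr2c (ENSMUSG00000041380) on chromosome X from 146962513 to 147197277. Htr1f (ENSMUSG00000050783) lies on chromosome 16 from 64924729 to 65105854, Htr4 (ENSMUSG00000026322) on chromosome 18 from 62324204 to 62496577, and Htr7 (ENSMUSG00000024798) on chromosome 19 from 35958734 to 36057507. All 5 are annotated as protein-coding genes, and values count UMIs over the whole gene.

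Activity genes were higher in excitatory than in inhibitory nuclei. Of 15 late activity and plasticity genes, 9 were at least 2-fold higher and none was called lower, with a median log2 ratio of 1.80, above all 10000 random lists of matched expression. Bdnf, a neurotrophin released by active neurons, stood at 45.8 against 9.53 CPM (log2 ratio 2.27, 2.00 to 2.54). Dusp5, a phosphatase acting on ERK kinase, had a ratio of 2.23, and Baz1a one of 3.22 on 9 inhibitory UMIs. Of 19 immediate early genes, 5 were higher and none was called lower, with a median of 0.63, also above all random lists. Egr3, a transcription factor, stood at 40.1 against 11.0 CPM (1.87, 1.62 to 2.13), Nr4a3, an orphan nuclear receptor, at 1.81 (1.56 to 2.08), and Arc, which regulates synaptic glutamate receptors, at 1.60 (1.40 to 1.81). Thinned to 1500 UMIs per nucleus, Baz1a was at 1.80.

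**Figure D2:**
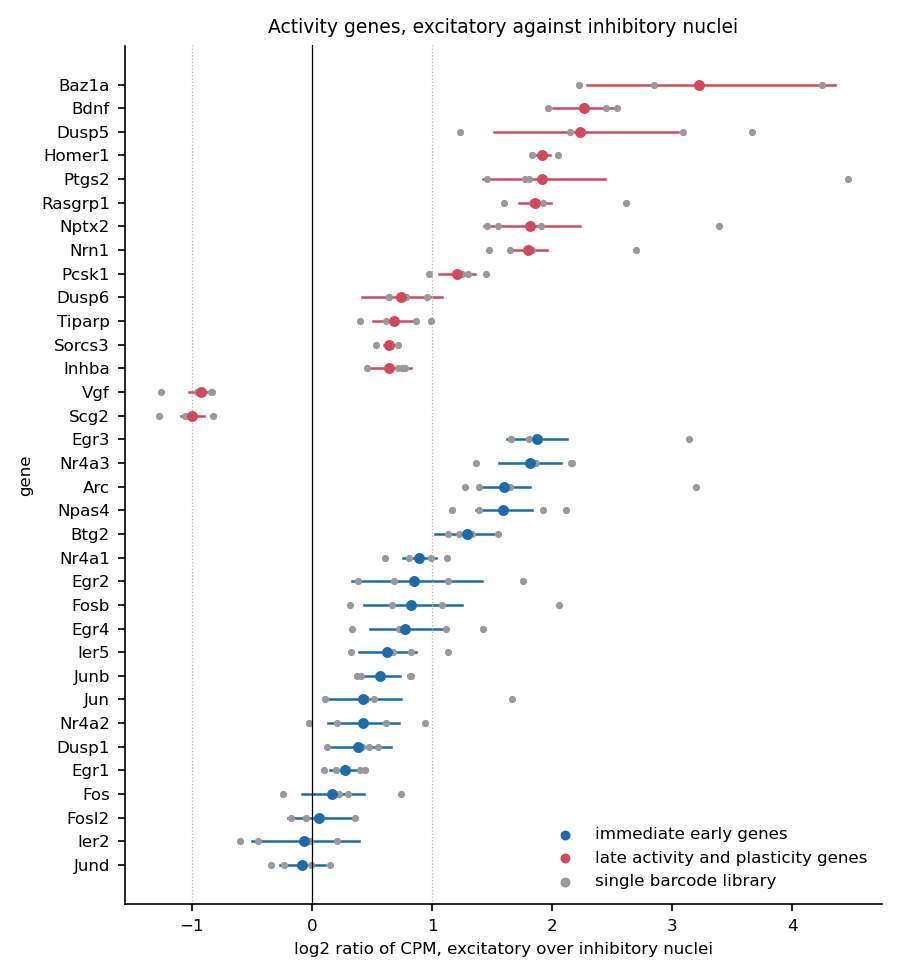
Log2 ratio of CPM, excitatory over inhibitory nuclei, for immediate early genes and for late activity and plasticity genes, with 95% counting intervals (lines) and single barcode libraries (grey points). Dotted lines mark a 2-fold difference; Bdnf lies at 2.27 and Egr3 at 1.87.

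Of 14 ionotropic glutamate receptor genes, 4 were lower in excitatory nuclei and 1 was higher (median 0.41). Grik1, a kainate receptor subunit, was at 50.8 against 1608 CPM (log2 ratio -4.99, -5.03 to -4.94), and the NMDA receptor subunits Grin3a (-3.46) and Grin2d (-2.18) were also lower. Of 7 metabotropic glutamate receptor genes 2 were higher, Grm8 at 1.97 and Grm2 at 1.51, and Grm2 stood at 0.61 after thinning. Of 16 postsynaptic scaffold and kinase genes 4 were higher, among them Dlg1 (1.60), Camk2a (1.52) and Nlgn1 (1.32). Of 17 genes of Gq signalling, the pathway of Htr2a, 3 were higher, among them Itpr1 (1.18), a calcium channel of the endoplasmic reticulum, and the kinase gene Prkcb (1.09). Of 12 GABA-A receptor subunits 1 was higher (Gabra5, 1.04) and 2 were lower (Gabrg1, -1.46, and Gabrd, -1.15). Of 5 neurotrophin genes 1 was higher, Ntf3 at 1.09 (0.31 to 1.98, on 14 inhibitory UMIs), and 1 was lower. Of 15 other monoamine, opioid, cannabinoid and muscarinic receptor genes 1 was higher and 4 were lower, including the delta opioid receptor Oprd1 (-2.19), the dopamine receptor Drd2 (-1.81) and the adrenergic receptor Adra1a (-1.74). Of 10 stress and glucocorticoid genes 2 were lower, the mineralocorticoid receptor Nr3c2 at -1.10 and the heat shock gene Hspa1a at -1.23. Nr3c2 stood at -0.18 with a clustering resolution of 0.5 and at -0.21 with up to 20% mitochondrial UMIs. There the inhibitory side again held only Pvalb-like and Sst-like nuclei. Grin3a, Grin2d, Gabra5, Hspa1a and Baz1a each overlap another gene, so their values are uncertain. In all, 43 of 140 list genes had a pooled ratio of at least 2-fold with the same sign in every library, 28 higher and 15 lower. Over all genes, the largest ratios outside the marker lists on the excitatory side were Olfr115 (6.13, 3.65 to 11.44, on 1 inhibitory UMI), Trabd2b (5.15, 4.61 to 5.75), Trbc1 (5.02, 3.16 to 8.07, on 2), Dnase1l3 (4.73, 3.37 to 6.61, on 4) and C7 (4.44, 2.88 to 6.72, on 3). With so few inhibitory UMIs their size and order are unsettled. On the inhibitory side they were Tmem132cos (-9.59), Erbb4 (-9.41, a neuregulin receptor), Sox2ot (-7.36), Ankrd55 (-6.87) and Adarb2 (-6.70). Genes outside the lists took part in the clustering, so these last ratios are not independent of how the classes were made.

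Neurons were then set against non-neuronal nuclei. Of 10 serotonin receptor genes 5 were higher and none was called lower: Htr4 at 36.2 against 5.54 CPM (log2 ratio 2.71, 2.32 to 3.12), Htr1f at 2.54 (2.41 to 2.68), Htr7 at 2.12 (1.41 to 2.93), Htr2c at 2.01 (1.77 to 2.25) and Htr2a at 44.1 against 13.3 CPM (1.72, 1.47 to 1.99). Of 15 ionotropic glutamate receptor genes 9 were higher, led by Grin2a (3.03), and 1 was lower, Grin2c (-6.18, -6.52 to -5.85), an NMDA receptor subunit found in astrocytes. Of 7 metabotropic receptor genes 5 were higher, with Grm8 at 2.97, and 1 was lower. Of 12 GABA-A subunits 8 were higher and 1, Gabrg1 (-2.75), was lower. Of 16 scaffold and kinase genes 7 were higher, Shank2 at 2.26 among them, and Homer3 was lower at -3.31. Of 15 other receptor genes 6 were higher, with Oprd1 at 3.31 and the muscarinic receptor Chrm3 at 2.78. Of 17 Gq signalling genes 3 were higher and 5 lower, the latter including the phospholipases Plcb3 (-2.87) and Plcb2 (-2.45). Of 5 neurotrophin genes 2 were higher, and of 16 late activity genes 5 were higher and 2 lower. Of 20 immediate early genes 4 were higher, among them Npas4 (1.77), a transcription factor induced by neuronal activity, and 1 was lower. Of 10 stress and glucocorticoid genes 5 were lower in neurons and none was called higher. Tsc22d3, a glucocorticoid-induced gene, stood at 4.28 against 122 CPM (-4.83, -4.99 to -4.68), and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 51.4 against 288 CPM (-2.49, -2.55 to -2.42). Homer3 and Plcb3 overlap another gene and are uncertain. In all, 71 of 143 list genes differed, 54 higher and 17 lower. Outside the marker lists the largest ratios in neurons, in no settled order, were Dcdc2c (4.52, 2.66 to 7.57, on 2 non-neuronal UMIs), Zim3 (3.98, 2.75 to 5.61, on 5), Olfr239 (3.91), Tex47 (3.75, 2.52 to 5.37, on 5) and Scn9a (3.66). Lower in neurons were Bcas1os2 (-9.51), Adap2 (-8.71), Cdh19 (-8.52), Runx1 (-8.36) and Prr5l (-8.33). Neuronal transcripts in non-neuronal nuclei, whatever their source, make the ratios of genes higher in neurons uncertain in size. With doublets kept the ratio fell to 0.55 for Htr7 and to 0.06 for Ntf3.

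To ask which excitatory neurons carry serotonin receptors, each excitatory subclass was set against the other excitatory subclasses together. Htr2a was highest in L6b-like nuclei, at 138 against 38.7 CPM (log2 ratio 1.83, 1.66 to 2.00), and in L6 IT-like nuclei, at 95.1 against 32.3 CPM (1.56, 1.46 to 1.66). It was lower in L6 CT-like nuclei, at 9.99 against 53.4 CPM (-2.42, -2.60 to -2.24), and in L5/6 NP-like nuclei, at 13.1 against 42.3 CPM (-1.69, -2.13 to -1.28). L5 IT-like (46.1 CPM), L2/3 IT-like (44.8 CPM) and L5 ET-like nuclei (30.4 CPM) lay between. All 4 called directions were present in each library. An Htr2a UMI was found in 63.7% of L6b-like nuclei (median depth 11748 UMIs), 49.2% of L6 IT-like (10568) and 7.33% of L6 CT-like nuclei (9862), beside 2.16% of oligodendrocyte-like (2693), 4.02% of astrocyte-like (3597) and 5.84% of microglia-like nuclei (2413). The microglia-like share was 20.7% in library 4 and 1.96% to 3.65% in the others. With nuclei thinned to 1500 UMIs the shares were 16.2%, 12.5% and 1.497% in those neurons, 1.91% in L5/6 NP-like and 2.03% in microglia-like nuclei. Thinning leaves shallow nuclei a larger part of free RNA, so whether the low values of L6 CT-like and L5/6 NP-like nuclei are background stays open. The L6b ratio was 1.22 with at least 1000 genes per nucleus and 0.95, short of 2-fold, with automatic doublet thresholds.

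Other serotonin receptors marked other subclasses. In L5/6 NP-like nuclei Htr2c stood at 887 against 18.9 CPM (log2 ratio 5.55, 5.47 to 5.64) and Htr4 at 382 against 23.6 CPM (4.02, 3.92 to 4.12). Htr4 was also higher in L5 ET-like nuclei, at 103 against 25.8 CPM (2.00, 1.90 to 2.10), and was lower in the L2/3 IT-like (-2.60), L5 IT-like (-3.08), L6 CT-like (-1.68), L6 IT-like (-4.21) and L6b-like classes (-2.21). Htr1f was higher in L6 CT-like nuclei, at 578 against 212 CPM (1.45, 1.41 to 1.48), and lower in L2/3 IT-like nuclei, at 53.9 against 370 CPM (-2.78, -2.88 to -2.68). Htr7 was higher in L6 CT-like nuclei (9.01 against 3.27 CPM, 1.46), Htr1b in L2/3 IT-like nuclei (13.4 against 6.12 CPM, 1.13) and Htr6 in L6 IT-like nuclei (3.33 against 1.61 CPM, 1.05, on 44 UMIs). Htr1d had 43 of its 74 UMIs in L6b-like nuclei, under the minimum of 100. In microglia-like nuclei Htr1f stood at 131 CPM, Htr2c at 32.2, Htr2a at 27.3, Htr4 at 16.4 and Htr7 at 3.82 CPM. Without library 4 the Htr6 ratio of L6 IT-like nuclei was 0.49, and with automatic doublet thresholds the Htr4 ratio of L6b-like nuclei was -0.67, both short of 2-fold. At a resolution of 2.0 the Htr4 ratio of L2/3 IT-like nuclei was -5.11, and the Htr2c ratio of L5 IT-like nuclei, -1.04 as reported, was -3.18.

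**Figure D3:**
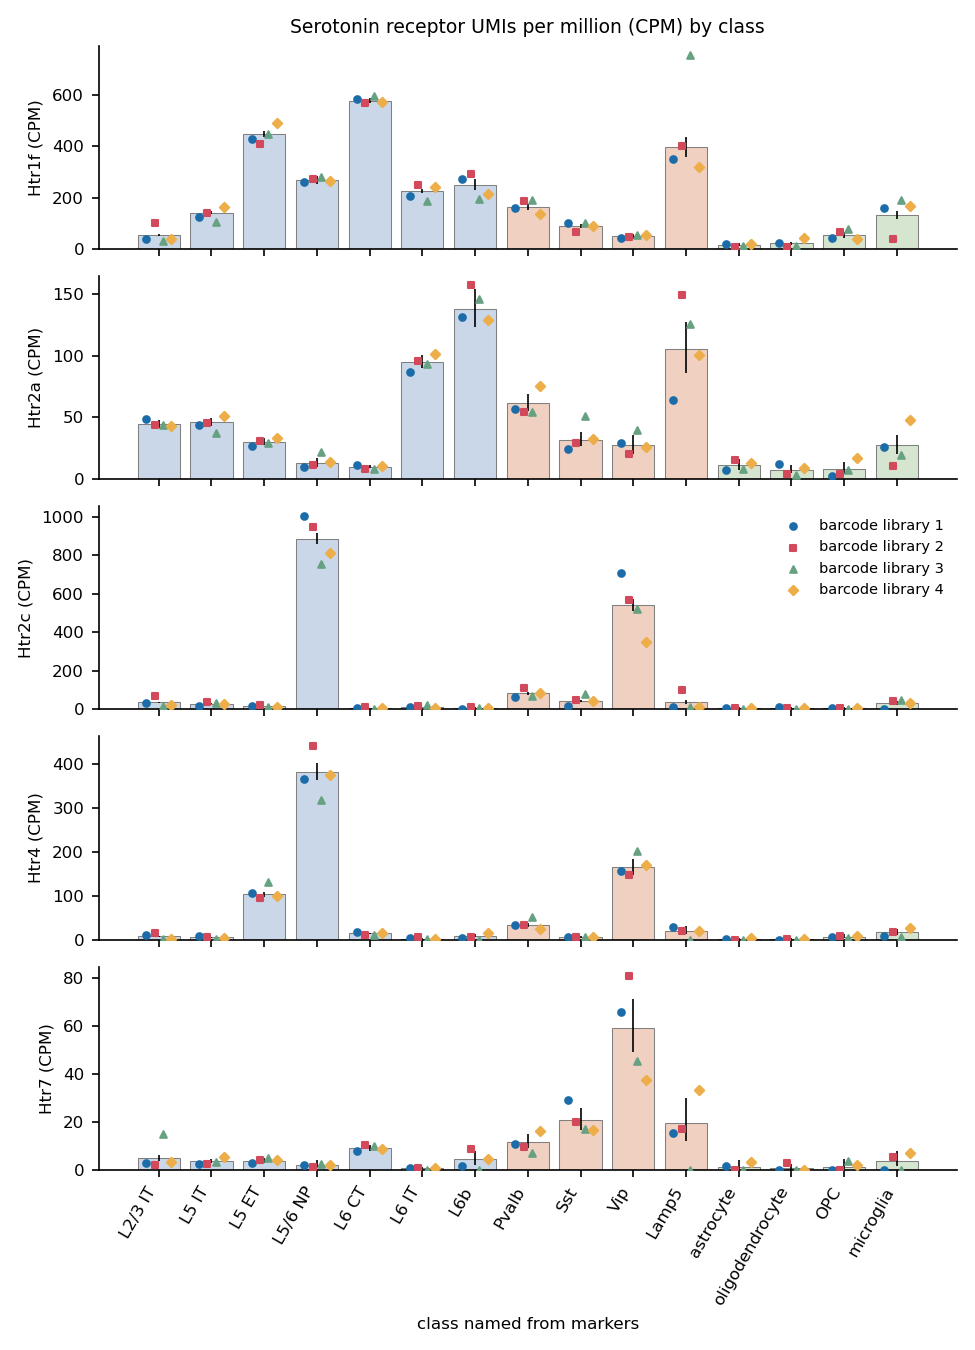
CPM of 5 serotonin receptor genes in neuronal subclasses and glia, for all nuclei (bars, with 95% counting intervals) and each barcode library (points); blue bars are excitatory, orange inhibitory and green non-neuronal. Htr2c stands at 887 CPM in L5/6 NP-like and 541 CPM in Vip-like nuclei, and Htr2a at 138 CPM in L6b-like nuclei.

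The remaining lists also differed between excitatory subclasses. L2/3 IT-like nuclei had 11 higher and 13 lower genes of 137, among them the neurotrophin Ntf3 (4.93, 4.38 to 5.53), Baz1a (2.64), the immediate early gene Egr2 (1.39) and Inhba (1.34), an activin subunit, on the higher side, and the kainate receptor gene Grik3 (-4.84) on the lower. L5 IT-like nuclei had 4 higher and 13 lower genes, with the cannabinoid receptor Cnr1 at 1.75 and the receptor kinase Grk5, which overlaps Zfp950, at 1.67. L5 ET-like nuclei had 4 higher and 13 lower, with Nr3c2 at 400 against 85.9 CPM (2.22, 2.17 to 2.27), Grik2 at 1.49 and the muscarinic receptor Chrm2 at -3.38. Their immediate early genes had a median log2 ratio of -0.40, below all 10000 random lists, though none of the 19 reached 2-fold. In L5 IT-like nuclei that median was 0.15, above 99.99% of random lists, with no gene called. Late activity genes had a median of 0.25 in L5 IT-like and in L6 IT-like nuclei, above 99.98% and 99.99% of random lists. Such ranks were not particular to activity genes. In L2/3 IT-like nuclei scaffold and kinase genes lay above 99.92% of random lists, and the other receptor genes above only 0.04%. L5/6 NP-like nuclei had 13 higher and 30 lower, with Grik1 at 1176 against 5.27 CPM (7.80, 7.66 to 7.94) and Chrm2 at 3.16, against Ntrk3 (-3.89), the receptor of Ntf3, and Chrm3 (-3.66). In that subclass 4 of 19 immediate early genes and 8 of 15 late activity genes were lower, and 1 late activity gene was higher. L6 CT-like nuclei had 7 higher and 23 lower, with Plcb4 at 1.77, Grik3 at 1.49 and the kinase gene Sgk1 at 1.34, and 5 of 15 late activity genes lower. L6 IT-like nuclei had 5 higher and 10 lower, with Chrm2 at 1.69, Sorcs3 at 1.54 and Ptgs2 at 1.37. L6b-like nuclei had 7 higher and 41 lower, with the dopamine receptor Drd1 at 33.2 against 6.98 CPM (2.25, 1.89 to 2.59). In L6b-like nuclei 7 of 19 immediate early genes were lower and 1 higher, and 7 of 15 late activity genes were lower. In simulated data with counting error only and no difference, 2.19% of genes were called in L6b-sized groups, more than in larger classes. With L6b-like nuclei thinned, the 48 called genes became 29. Leading ratios over all genes were Olfr115 in L6b-like (8.64), Lcp1 in L5/6 NP-like (7.09), Shoc1 in L5 ET-like (5.93), Glis3 in L2/3 IT-like (5.20), Tg in L6 CT-like (4.40), BC006965 in L5 IT-like (4.32) and Tll2 in L6 IT-like nuclei (3.01).

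Inhibitory subclasses were compared in the same way. Vip-like nuclei carried 3 serotonin receptors at higher levels: Htr2c at 541 against 63.3 CPM (log2 ratio 3.10, 2.96 to 3.24), Htr4 at 165 against 21.7 CPM (2.92, 2.68 to 3.18) and Htr7 at 59.4 against 15.9 CPM (1.90, 1.54 to 2.25). Htr3a, the ionotropic serotonin receptor, had 39 of its 40 inhibitory UMIs there, under the minimum of 100. Lamp5-like nuclei had higher Htr1f, at 397 against 117 CPM (1.76, 1.59 to 1.92), and higher Htr2a, at 105 against 45.5 CPM (1.21, 0.90 to 1.51). Htr2a was at 61.9 CPM in Pvalb-like, 31.8 CPM in Sst-like and 27.4 CPM in Vip-like nuclei, none of them called higher or lower. Vip-like nuclei had 17 higher and 18 lower genes of 114, with Sorcs3 at 3.51, Cnr1 at 3.49, Nr3c2 at 2.35 and the prohormone convertase Pcsk1 at 2.32. In them 4 of 15 immediate early genes were higher and none was called lower, including Nr4a1 at 81.6 against 28.4 CPM (1.52, 1.23 to 1.80), with a median of 0.45, above all random lists. Pvalb-like nuclei had 5 higher and 22 lower genes, with Gabrd at 2.06, Ntrk3 at 2.04 and Oprd1 at 1.73, against Grin3a (-3.75) and Cnr1 (-3.22). Sst-like nuclei had 8 higher and 15 lower, with Grin3a at 1035 against 73.9 CPM (3.81, 3.69 to 3.93) and Grik3 at 2.45. Lamp5-like nuclei had 15 higher and 19 lower, with Homer2 at 2.76, Grin2a at 2.26 and Grk5 at 2.18. Leading ratios over all genes were Unc13c in Sst-like (6.51), Pde11a in Lamp5-like (5.46), Adarb2 in Vip-like (4.90) and Myo1e in Pvalb-like nuclei (4.68). At a resolution of 0.5 Vip-like and Lamp5-like nuclei had no cluster of their own, so Pvalb-like nuclei were compared with Sst-like nuclei alone. The Htr2c ratio of Pvalb-like nuclei, -1.10 as reported, was then 0.99. Thinned to 1500 UMIs, the Htr7 ratio of Vip-like nuclei was 1.06. None of the fixed Sst markers was among the 10 leading genes of the Sst-like cluster, which included the Lamp5 marker Reln.

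Because libraries could not be assigned to samples, the lists are given per library as values only. Summed immediate early genes in excitatory nuclei stood at 500.1, 416, 487 and 494 CPM in libraries 1 to 4, with a median of 490.3. In inhibitory nuclei they ranged from 221 to 295 CPM with a median of 266, and in non-neuronal nuclei from 340.5 to 485 CPM with a median of 455. Late activity genes in excitatory nuclei stood at 1664, 1687, 1907 and 1601 CPM. Serotonin receptors in excitatory nuclei stood at 496, 512, 452 and 496 CPM. Stress and glucocorticoid genes in excitatory nuclei ranged from 642 to 858 CPM with a median of 784, and in non-neuronal nuclei from 1586 to 1912 CPM with a median of 1806.

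The reporter transcript (feature TREmcherry) was measured to ask which classes the activity-gated tool had marked. At least 1 UMI was found in 820 of 8247 excitatory nuclei (9.94%, 9.31 to 10.6), in 118 inhibitory nuclei (9.03%, 7.53 to 10.7) and in 156 non-neuronal nuclei (5.63%, 4.80 to 6.55). Microglia-like nuclei, which should lack it if the tool acts in neurons, had 5.47% at a median depth of 2413 UMIs against 10884 in excitatory nuclei. This microglia-like share differed between libraries, at 0%, 7.37%, 1.96% and 13.043% in libraries 1 to 4. With nuclei thinned to 1500 UMIs the order turned, to 1.496% of excitatory, 1.69% of inhibitory and 2.85% of non-neuronal nuclei. Globin UMIs, a measure of free RNA, were about as many per 100 excitatory nuclei as per 100 nuclei of the named non-neuronal classes (18.1 and 17.1 in library 1, 63.9 and 66.8 in library 4), so free RNA weighs more in shallow nuclei after thinning. The turned order therefore does not settle where the reporter UMIs came from. By subclass the unthinned share was highest in L2/3 IT-like (12.2%) and L5 IT-like nuclei (12.1%). In excitatory nuclei it was 4.80%, 13.7%, 4.24% and 13.8% in libraries 1 to 4. Of 1116 nuclei with the transcript, 87.4% had exactly 1 UMI. The 3 nuclei with more than 10, at 18, 36 and 209 UMIs, were in library 4 and in the L2/3 IT-like cluster, and they held 17.1% of all TREmcherry UMIs in kept nuclei. The second transgene, tTA, was found in 2.995% of excitatory, 3.52% of inhibitory and 1.37% of non-neuronal nuclei, and in 0.474%, 0.536% and 0.703% after thinning.

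**Figure D4:**
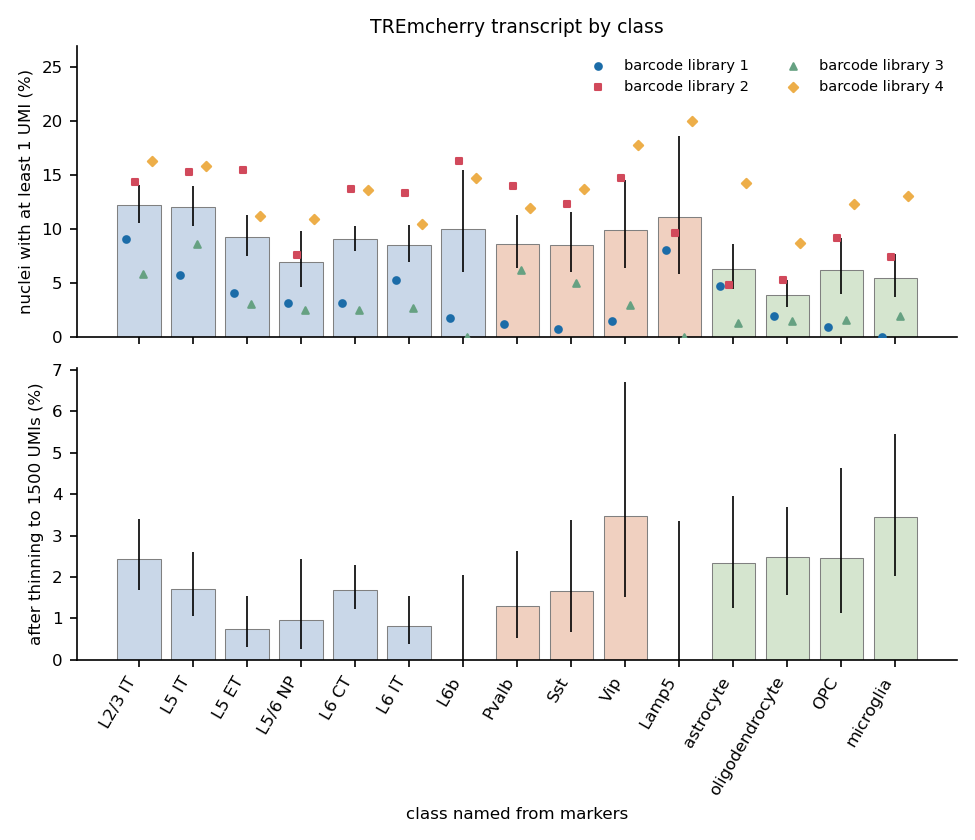
Share of nuclei with at least 1 TREmcherry UMI in each class, in percent, over all UMIs (upper panel, points are barcode libraries) and after thinning each nucleus to 1500 UMIs (lower panel), with exact 95% intervals; blue bars are excitatory, orange inhibitory and green non-neuronal. L2/3 IT-like nuclei stand at 12.2% above and 2.44% below, and microglia-like nuclei at 5.47% and 3.45%.

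Within each of 6 excitatory classes with at least 50 reporter-positive nuclei, positive nuclei were compared with negative ones, to ask whether marked neurons differ in receptor or activity genes. Few list genes were called, all of them lower in positive nuclei: Nr4a2 in L2/3 IT-like (log2 ratio -1.64, -2.98 to -0.56), Egr4 in L5 IT-like (-1.01, -1.71 to -0.39), Fosl2 in L5 ET-like (-1.23, -2.57 to -0.15), Htr4 (-1.19) and Ier2 (-1.11) in L6 CT-like, Rgs2 in L6 IT-like (-1.21, -2.85 to 0.05) and Egr3 in the nuclei with no subclass (-1.14). None was called higher. Htr2c in L5 ET-like nuclei (1.03) and Grik1 in the nuclei with no subclass (1.51) were at least 2-fold higher without the same sign in every library. The positive side held 5 to 22 UMIs of each, and only Egr4 and Egr3 had UMIs on both sides in all 4 libraries. Ratios pool the libraries, whose positive share of excitatory nuclei ran from 4.24% to 13.8%, so library and reporter state are partly mixed. Taken within libraries, the Egr4 ratio was -0.99, short of 2-fold. A library without positive UMIs counts as lower under the rule, so for the other 5 genes the call follows in part from sparse counts. The share of nuclei with an Htr2a UMI was 33.1% of positive and 26.7% of negative L2/3 IT-like nuclei, and 43.2% and 49.8% of L6 IT-like nuclei, with overlapping intervals. Within libraries the median depth of positive nuclei was 0.962 to 1.38 times that of negative ones. After thinning no gene was called in L2/3 IT-like or L6 CT-like nuclei, and other genes than these were called in the remaining classes.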

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

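Of the tests in this part, those on the depth of nuclei, on clustering of striatal nuclei and on free RNA for Htr2b were chosen after the result had been seen. Of biological explanations, only joint expression of both transgenes was tested.

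Both transgenes were also found in the 9132 barcodes that the filters left out of the comparisons. TREmcherry had 1025 UMIs there, in 887 barcodes, and tTA had 194 UMIs in 184 barcodes, each above a set floor of 3 counts. TREmcherry stood at 40.0 CPM in these barcodes and 12.2 CPM in kept nuclei, and tTA at 7.56 and 4.08 CPM. Per 100 barcodes, TREmcherry had 4.37, 16.8, 2.77 and 14.035 UMIs in these and 4.17, 13.9, 3.89 and 22.3 in kept nuclei of libraries 1 to 4, with no direction shared by the libraries.

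Reporter UMIs occurred in every cell class. In pooled CPM, excitatory nuclei of at most 5 TREmcherry UMIs stood at 0.58 (0.488 to 0.694) times the named non-neuronal classes, but free RNA raises CPM in shallow nuclei, so this value leaves depth as a cause of the higher excitatory share open. Measured against globin, whose UMIs in these nuclei stand for free RNA, TREmcherry in excitatory nuclei of at most 5 TREmcherry and 10 globin UMIs was 1.83 (1.52 to 2.25) times that in such nuclei of the named non-neuronal classes, and 1.90, 2.49, 3.95 and 1.22 times in libraries 1 to 4 (tTA 2.39, 1.66 to 3.65). The TREmcherry value lies between the bounds set beforehand, 1.5 for free RNA as the whole source and 2.0 against it. In these nuclei free RNA and expression in neurons therefore cannot be told apart. The tTA value passed 2.0, but the bounds were set for TREmcherry alone. By library tTA stood at 6.58, 2.33, 16.6 and 1.28 times, on 2, 18, 1 and 15 non-neuronal UMIs. Nuclei of more than 5 TREmcherry UMIs, with up to 209 of them, lie outside this test. Excitatory nuclei of at most 5 TREmcherry UMIs with both transgenes numbered 52 against 30.2 expected, 1.72 (1.29 to 2.26) times, which falls between its bounds of 1.2 and 2.0 and leaves expression in a minority of nuclei open.

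Striatal medium spiny neuron-like nuclei numbered 220, 77, 32 and 1 in libraries 1 to 4. The mitochondrial filter did not remove them from library 4, whose share was 0.028% with up to 20% mitochondrial UMIs. Clustering did not hide a set as large as that of library 1 there. The markers that come mostly from this class (Rgs9, Adora2a, Rarb and Isl1) stood in library 4 at 0.31 (0.295 to 0.326) times the CPM of library 1. Together they stood at 171, 110, 125 and 53.0 CPM in libraries 1 to 4. Their summed level outside the class was not measured, so a smaller hidden set in library 4 is not excluded. A first form of that test, with all striatal markers, was void, because 83.5% of their CPM in library 1 came from outside the class. A difference in how much neighbouring tissue was dissected could account for them and was not tested.

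Htr2b had a like level in every named class, from 33.6 CPM in Vip-like to 49.1 CPM in microglia-like nuclei. Whether UMIs of Psmd1, which overlaps it on the opposite strand, are the source could not be decided. The ratio of Htr2b to Psmd1 varied 1.59 times over the classes with at least 50 Htr2b UMIs, within the limit of 2.0 set beforehand. Any evenly expressed gene would give a like result, so this ratio does not point to Psmd1. The microglia-like level was 1.17 (0.937 to 1.44) times the excitatory one. Free RNA as the only source in every class would give more in shallow nuclei, so this value argues against it. Free RNA in glia beside expression in neurons stays open, since Slc17a7 stood at 234 CPM in microglia-like and 247 CPM in excitatory nuclei.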

How the results depend on the processing

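Chosen after seeing the data were the limit of 20% mitochondrial UMIs, the automatic doublet thresholds, and for the reporter the ratio within libraries and the limit of 5 UMIs. Of 178 alternatives for the 13 counts of called genes, 176 gave a count within 1.5 times the reported one, and 4 opposite calls of a gene occurred over all of them. The exceptions came with thinning to 1500 UMIs, where L6b-like nuclei had 29 called genes (25 shared with the reported 48) and Vip-like nuclei 21 (20 shared with 35). A like count does not mean the same genes. The fewest shared in any alternative were 9 of 15 in L6 IT-like, 14 of 23 in Sst-like, 20 of 30 in L6 CT-like and 15 of 17 in L5 ET-like nuclei. Vip-like and Lamp5-like nuclei gave no value at resolution 0.5 and at 20% mitochondrial UMIs. The excitatory share was 62.8% with doublets kept, 65.8% with at least 1000 genes, 84.1% with at most 1% mitochondrial UMIs and 59.983% to 65.6% without 1 library. The inhibitory share was 9.51% at 1% and 8.02% at 20% mitochondrial UMIs, and 9.80% to 10.5% without 1 library. The non-neuronal share was 22.7% with doublets kept, 19.1% with at least 1000 genes, 3.99% at 1%, 25.3% at 20% and 20.1% to 24.3% without 1 library. Immediate early genes in excitatory nuclei stood at 611, 502, 593 and 600.3 CPM in libraries 1 to 4 without mitochondrial and the 20 most abundant genes, since a smaller total divides them. TREmcherry shares with at least 2 UMIs, with thinning and without 1 library were 1.37%, 1.496% and 8.04% to 12.3% of excitatory nuclei, 0.995%, 1.69% and 6.78% to 12.2% of inhibitory nuclei, and 0.505%, 2.85% and 3.99% to 7.16% of non-neuronal nuclei. Reporter-positive nuclei after thinning had 0 called genes in L2/3 IT-like and L6 CT-like nuclei and 2 in those with no subclass, and by ratios within libraries 0 in L5 IT-like and 2 in L5 ET-like nuclei. Of 4198 alternative values for 309 gene ratios, 948 left the interval of the reported ratio, among them 147 with thinning, 125 with doublets kept and 191 without 1 library, and 10 turned sign: Grm2 in L6b (0.48, thinned), Htr6 in L6b (0.015 with at least 1000 genes, 0.056 with automatic doublet thresholds), Htr2c in Pvalb (0.99 at resolution 0.5, 0.52 at 20%), Inhba in Pvalb (0.72 and 0.79), Sorcs3 in Sst (1.14 and 1.115) and Adra1b in Sst (0.058 at 20%). At resolution 0.5 and at 20% mitochondrial UMIs, Pvalb-like and Sst-like nuclei were compared only with each other, since Vip and Lamp5 clusters were missing. The cause of the changes was not tested. The 8 other settings for DOI against saline were not run, because barcodes name no sample. Depth limits Htr1d, Htr3a and Htr5b, each with under 100 UMIs in neurons.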

Other observations

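No test was made for the patterns below, which were chosen after the values had been seen.

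Xist, the RNA of the inactive X chromosome, had 8, 32540, 16278 and 7 UMIs in kept nuclei of libraries 1 to 4, and its antisense gene Tsix had 30, 14625, 12116 and 30. The Y-linked gene Uty had 3932, 6, 3 and 4641 UMIs, Eif2s3y 3655, 0, 0 and 3254, Kdm5d 1716, 0, 1 and 1720, and Ddx3y 1200, 2, 0 and 1348. No library was assigned to a sample from these values.

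Neuroblast-like nuclei made up 2.80%, 2.38%, 0.957% and 0.352% of libraries 1 to 4. Their cluster held Top2a, a gene of dividing cells, among its 10 leading genes, with Dcx, Sox11, Igfbpl1 and Meis2 as enriched markers. Striatal medium spiny neuron-like nuclei, which had an Htr2a UMI in 21.8% of 330 nuclei at a median depth of 6604 UMIs, made up 5.27%, 2.23%, 2.04% and 0.027%. Microglia-like nuclei, at a median depth of 2413 UMIs, had an Htr2a UMI in 5.84% of nuclei, and in 20.7% in library 4.

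The nucleus with 209 TREmcherry UMIs also held 119 tTA UMIs among 18333 UMIs in total. The nuclei with 18 and 36 held 9 and 1 tTA UMIs. They held 0 or 1 UMI of Slc17a7.

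TREmcherry in kept nuclei stood at 5.10, 14.9, 3.48 and 19.7 CPM in libraries 1 to 4, and tTA at 1.64, 4.66, 2.11 and 6.43 CPM. In library 4, the 3 nuclei with more than 10 TREmcherry UMIs held 263 of 823 TREmcherry UMIs and 129 of 269 tTA UMIs, so the rank of that library rests on them.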
